A study of Homo sapiens with 8 samples.

How the data were processed

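IRF8, a transcription factor of the interferon regulatory factor family, was immunoprecipitated with its bound chromatin from 4 human cell lines, and the DNA was compared with input DNA of the same line on tiling arrays (ChIP-chip). Per the labels, LY1, ODH1 and VAL are IRF8-positive and MMS1 is IRF8-negative and serves as the negative control. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sonicated, and ChIP and input DNA were joined to linkers and amplified by PCR before labelling. Each line was hybridised once to a set of 2 promoter arrays that carry different regions, giving 8 hybridisations. ChIP DNA carried Cy5 and input DNA Cy3 on every array, with no dye swap, so a dye effect does not cancel.

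The deposited files of each array hold the intensity of every probe in each channel on a linear scale, written by NimbleScan 2.3.78 per the file headers; whether a background was subtracted is not given in the sources used here. The authors' value table, also deposited, holds log2 values. Set against the scanner files, each of its columns equalled log2(Cy5/Cy3) minus a constant per array, to within 0.00501, so its scale is log2 and its direction ChIP over input. The medians of its columns were 0 or 0.01, and the constants matched the Tukey biweight mean of each array. All scanner files carried the same scanning day, so no scan batch could be tested.

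The log2 ratio of ChIP over input was computed for 757904 experimental probes, after leaving out 10364 random-sequence probes on the first array design and 10346 on the second, and the median of each array was subtracted. No loess or quantile normalisation was applied. The probes fall in 23047 tiled regions with a median width of 4261 bp and a median of 32 probes, in hg18 coordinates. Windows of 500 bp starting every 250 bp were averaged where they held at least 4 probes, which left 243783 windows in 22953 regions, with a median of 5 probes. Values of both arrays were stacked, 1 column per cell line.

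Windows were tested with limma 3.58.1 in R 4.3.3, two-sided, in a group-means model with 3 IRF8-positive lines and MMS1. The mean of the positive lines was tested against 0 (enrichment over input) and against MMS1. The residual spread, with 2 degrees of freedom and 8.02 prior degrees of freedom, comes from the positive lines only, and MMS1, which has no replicate, is assumed to vary like them. Region p-values were combined over windows by Simes' method and adjusted by Benjamini-Hochberg at 0.05. A region was counted for both tests if it held a window past the adjustment over all windows in each. Nothing in the labels says how many cultures stand behind a hybridisation, so the p-values measure only the spread between these lines. Peaks in a single line were described, not tested: the lowest threshold of at least 0.5, in steps of 0.05, at which windows at or below its negative numbered at most 5% of those at or above it.

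The procedure was tested on simulated data with the real probe layout, in which 200 regions carried a known log2 rise in the positive lines. With 1 SD for all lines, 34% of regions with a simulated rise of 1 and 100% of those with a rise of 2 were called enriched. The test against MMS1 called 40% of the regions with a rise of 2 and 92% of those with a rise of 3, and among 22753 unaltered regions it called 0 higher and 1 lower. With the measured SD of each array it called 414 unaltered regions higher and 450 lower. In this simulation the test against MMS1 therefore did not hold its error rate with MMS1 noisier than the other lines, as it also is in the real data. With the measured SDs, 0 of the unaltered regions were called enriched and 0 passed both tests. The noise was drawn apart for each line, so the simulated lines shared no probe effects. These counts therefore do not measure the calls that probe effects shared between real arrays would give. Each array also had a single SD for all its probes, so differences in noise between probes were not simulated. How far the simulated shares and counts carry over to the real data is not known.

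Before the data were examined, the regions to be named were fixed. They were up to 25 ranked by the difference from MMS1 and the 5 with MMS1 furthest above the positive mean. The 3 highest windows of each line were also fixed for naming. Where fewer than 25 pass both tests, the rest are ranked by the lowest positive line minus MMS1 and are said not to pass. Windows on chromosome Y were left out of this naming after the values were seen, which removed 1 window. The files give positions and no gene names, and the gene table at hand is on GRCh38, so no position was converted and no gene was named. The 17 gene lists fixed beforehand and the named genes could therefore not be tested. Alternatives fixed beforehand covered background correction (normexp, offset 50), loess, Tukey biweight centring, equal scale, the authors' table, windows of 300 and 1000 bp, the median of probes, removal of the dimmest 10% of input probes, each positive line left out, eBayes with trend and robust settings, arrays fitted apart, a log2 minimum of 0.5, and for peaks a 1% rate or a fixed threshold of 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.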

Results

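IRF8 occupancy was measured at promoters in 3 IRF8-positive diffuse large B cell lymphoma lines, LY1, ODH1 and VAL, and in the IRF8-negative control line MMS1. The number of arrays, 2 per line with no repeat of either design, limits the precision. ChIP and input signals of a line correlated across probes with r of 0.942 and 0.953 on the LY1 arrays and 0.632 to 0.786 on the other arrays. The SD of the log2 ratio ranged from 0.327 on the second LY1 array to 0.97 on the second MMS1 array, and both MMS1 arrays had a larger SD than any array of the positive lines. Between 42.8% and 74.7% of the ChIP signals, and between 72.1% and 94% of the input signals, lay above the 95th percentile of the random-sequence probes of the same array. Across windows, which are not independent replicates, LY1 correlated with ODH1 at r = 0.37 and with VAL at 0.47, and ODH1 with VAL at 0.44. The correlations of MMS1 with these lines were 0.29, 0.3 and 0.28. By array design the gap narrowed in places: on the first, LY1 correlated with ODH1 at 0.34 and with MMS1 at 0.33, and on the second ODH1 correlated with LY1 at 0.45 and with MMS1 at 0.42, though at only 0.17 on the first.

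The first comparison asked which promoter regions were enriched over input in the IRF8-positive lines. In 235 of 22953 regions the mean of the 3 lines was above input, with a median log2 of 1.6 (3.03-fold) and a range of 0.97 to 2.71. The highest mean was at chromosome 19, 12585655 to 12585955 in hg18, where LY1 measured 2.63, ODH1 2.57 and VAL 2.93 (mean 2.71, SD 0.19, n = 3 lines; 6.54-fold; limma region adjusted p = 0.0012). A window on chromosome 20, 12938147 to 12938547, had a mean of 2.65 (SD 0.12, n = 3 lines; limma region adjusted p = 0.0012), and MMS1 measured 0.27 there. On chromosome 14, at 67353105 to 67353505, the mean was 2.59 (SD 0.39, n = 3 lines; limma region adjusted p = 0.0032). The enriched regions were split between the designs, 125 on the first and 110 on the second. A further 165 regions were below input, with a median of -1.14 and a range of -2.52 to -0.76, of which 145 were on the first design. By window, adjusted over all windows, the order was reversed, with 720 above input and 1223 below. The split of 235 higher and 165 lower moved with the scaling, to 241 and 0 after loess, 311 and 8 after normexp, and 854 and 2266 with arrays scaled to 1 spread. Without VAL 102 regions were enriched, without LY1 595 and without ODH1 1031, and with the trend and robust variance model none were (3030 at an unadjusted p under 0.05).

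At the 235 enriched regions MMS1 had a median log2 of -0.07, with quartiles of -0.56 and 0.34. It was below all 3 positive lines in 227 of them and below 0 in 128. In the other 8, MMS1 was at least as high as the lowest positive line. The regions were picked as high in those 3 lines, which by itself favours a lower MMS1 value. Over all windows MMS1 was above 0 in 47.1% and at least 1 in 3.67%. The counts of 227 and 128 therefore do not show that enrichment was lost with IRF8. At the 165 regions below input the MMS1 median was -0.57. That is close to its median of -0.55 over all 4876 windows at or above percentile 98 of the positive lines' input signal. In the same bright windows the positive lines had a median of -0.72, against -1.14 at the 165 regions, which were picked as low in those lines.

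**Figure D1:**
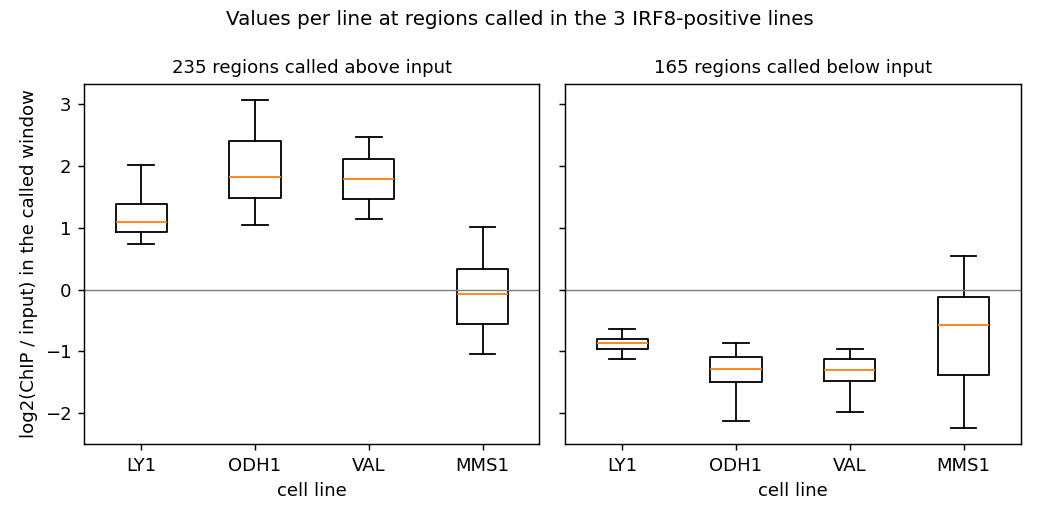
Log2 ratio of ChIP over input (y axis) in the called window of each region, by cell line (x axis), for the 235 regions above input (left) and the 165 below input (right); boxes show quartiles and median, whiskers the 5th and 95th percentiles. Regions were called on LY1, ODH1 and VAL, so their heights reflect that choice, while the MMS1 median of -0.07 on the left and -0.57 on the right does not.

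The second comparison, against the IRF8-negative line, asked whether enrichment went with the presence of IRF8. By region, limma called 0 higher and 0 lower in the positive lines than in MMS1 (smallest adjusted p = 0.0667). At an unadjusted p under 0.05 there were 2771 higher and 3941 lower regions, and at an adjusted p under 0.1 there were 937 and 1454, including 124 of the 235 enriched regions. These counts, and those of the alternatives, assume that MMS1 varied like the positive lines. In the simulation with the measured SDs, where it did not, the adjusted test called 414 unaltered regions higher and 450 lower. The real data gave 0 and 0, and the simulation had a single SD per array. Its counts therefore warn of false calls but do not estimate their number here. Without ODH1 the region counts rose to 3185 higher and 3420 lower, and without VAL to 183 and 247. They were also above 0 with the median of probes (502 and 889), with the trend and robust model (1241 and 3061) and with 1000 bp windows (3 and 0).

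Adjusted over windows, 3 windows in 3 regions were both enriched and higher than in MMS1, each with limma adjusted p = 0.048 for the difference. The largest difference, 3.78 (SE 0.32), was on chromosome 20 at 47327451 to 47327851, where LY1 measured 0.79, ODH1 1.18 and VAL 0.88 against -2.83 in MMS1. That difference came mostly from the low MMS1 value, and the region's own adjusted p for enrichment was 0.056. On chromosome 19, at 12585655 to 12585955, the difference was 3.62 (SE 0.32), with MMS1 at -0.91. On chromosome 12, at 54609445 to 54609845, LY1 measured 2.35, ODH1 2.08 and VAL 2.35 against -1.25 in MMS1, a difference of 3.51 (SE 0.32). In MMS1, 4 of 5 ChIP probes of the chromosome 20 window lay above the 95th percentile of the random-sequence probes, but only 2 of 4 on chromosome 19 and 1 of 4 on chromosome 12, so the MMS1 values of the latter windows, and the differences from them, rest partly on background signal. None of the 3 passed both tests with arrays scaled to 1 spread, where the adjusted p of the difference was 0.25, 0.41 and 0.42 (from 2.6e-06 to 0.42 over all settings, with differences of 2.92 to 4.31, 3 to 4.43 and 2.89 to 4.71), nor after loess, normexp, in 300 bp windows, with arrays fitted apart, without LY1, or with the trend and robust model. Without ODH1 the number past both tests was 495, without VAL 51, among them 2 of these 3, and with the median of probes 94.

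The other 22 of the 25 named regions did not pass both tests. Of all 25, 22 passed the region test for enrichment, and MMS1 was below 0 in each. On chromosome 1, at 9052283 to 9052583, the positive lines had a mean of 2.5 (SD 0.68, n = 3 lines) and MMS1 measured -1. On chromosome 4, at 110701665 to 110702065, the mean was 2.55 (SD 0.88, n = 3 lines), with the highest ODH1 value, 3.52, and MMS1 measured -0.72, with 1 of its 4 ChIP probes above the random-sequence level. On chromosome 11, at 1830575 to 1830975, the lines lay close together, at 1.96, 2.02 and 2.21, against -0.5 in MMS1. In 4 of the 25 windows, the chromosome 1 window included, no MMS1 ChIP probe was above the random-sequence level, so the MMS1 value there is not well above background.

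Some windows had MMS1 highest. On chromosome 1, at 52872149 to 52872449, MMS1 measured 3.3 and the positive lines had a mean of -0.13 (SD 0.29, n = 3 lines). On chromosome 9, at 719919 to 720219, MMS1 measured 2.52 and the positive mean was -0.65 (SD 0.21, n = 3 lines), but 0 of 4 ODH1 and 2 of 4 VAL ChIP probes were above the random-sequence level there, so that mean rests partly on background signal. Neither passed the window test (limma adjusted p = 0.062 for each). MMS1 has 1 hybridisation per design, so these values have no replicate check.

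**Figure D2:**
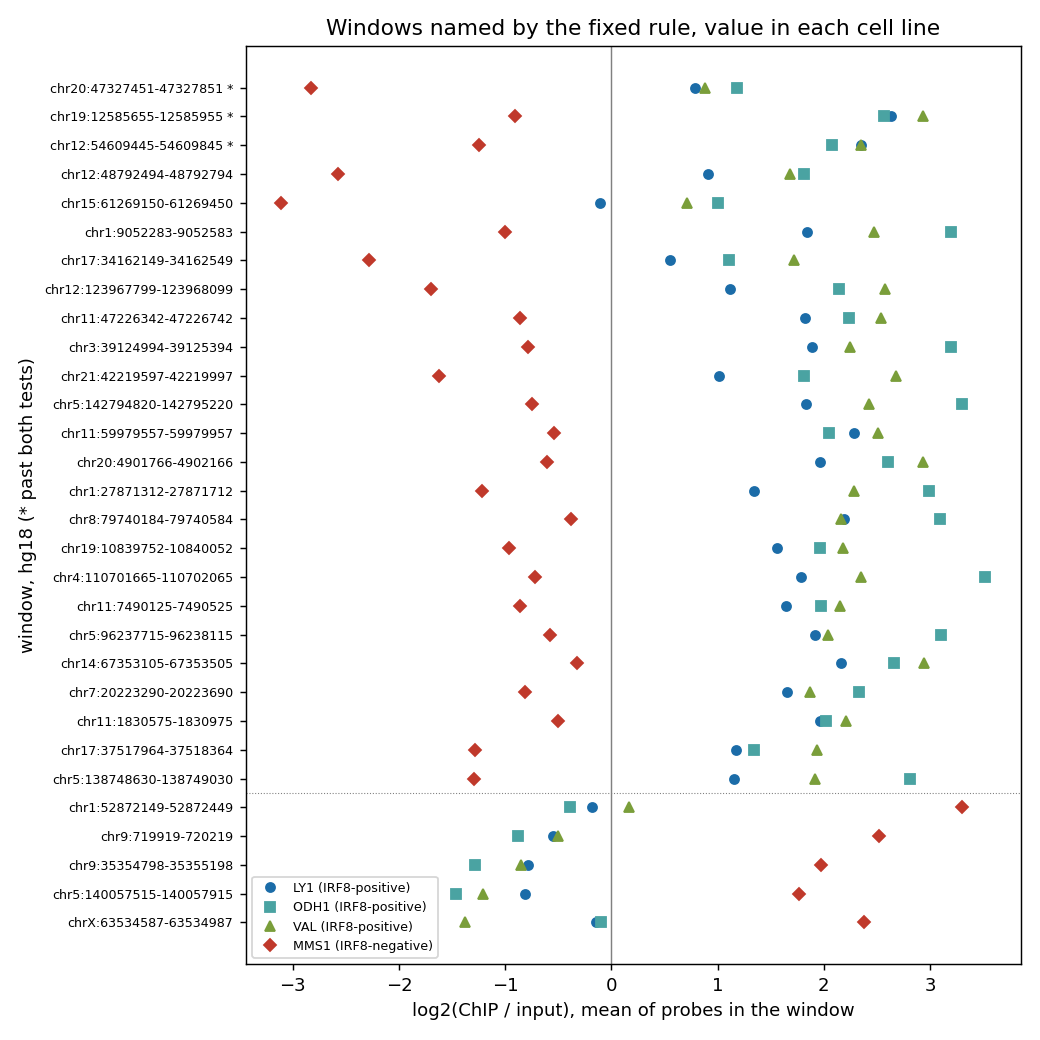
Log2 ratio of ChIP over input (x axis) in each of the 4 cell lines at the named windows (y axis, hg18 positions). Of the first 25, asterisks mark the 3 past both tests, ordered by the difference from MMS1. The rest are ordered by the lowest positive line minus MMS1. Under the dotted line are the 5 with MMS1 furthest above the positive mean. Windows were chosen for this separation; MMS1 lies below 0 in all 25 and reaches 3.3 on chromosome 1 among the 5.

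Single lines were then described by their own peaks. In LY1 366 regions held a window at or above its threshold of 1.15. In ODH1, VAL and MMS1 no threshold met the 5% rule, because the windows below the negative of each threshold stayed above 5% of those above it. At a distance of 1, ODH1 had 2850 windows above and 8835 below, VAL 2678 and 9158, and MMS1 8938 and 17511. At a distance of 2 VAL had 191 above and 167 below. The number with a peak in all 3 positive lines and none in MMS1 was therefore 0, which reflects the absence of thresholds and not of shared regions. Of the 366 LY1 regions, 107 were among the 235 enriched. At the LY1 peak windows ODH1 was at least 1 in 28.4% and VAL in 29.5%, against 1.17% and 1.1% of all windows. MMS1 was at least 1 in 4.37%, against 3.67% of all windows. At the lower level of 0, however, MMS1 was above input in 78.4% of the LY1 peak windows, against 47.1% of all windows, ODH1 in 71.3% against 45.9%, and VAL in 98.4% against 45.8%. The median at these windows was 0.34 in MMS1, 0.13 in ODH1 and 0.5 in VAL. With a fixed threshold of 1 the regions numbered 799 in LY1, 1671 in ODH1, 1591 in VAL and 5818 in MMS1, and 153 were shared by the 3 positive lines, where independent sets would give 4.03. MMS1 also had a peak in 50 of the 153 and none in the other 103, where independent sets would give 3.01. With 5818 of all 22953 regions holding an MMS1 peak, the 103 do not show that the sharing was specific to the positive lines.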

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

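A total of 3 regions passed the limma test of the difference between the IRF8-positive lines and MMS1 over windows, while the region test called 0; the tests of loess, of held-out lines and the bound for the regions below input were chosen after the values they measure were seen. The differences were 3.78 on chromosome 20 (region from 47324621), 3.62 on chromosome 19 (region from 12579252) and 3.51 on chromosome 12 (region from 54606413), and the windows were chosen for this difference. In MMS1 only 2 of 4 ChIP probes on chromosome 19 and 1 of 4 on chromosome 12 were above the random-sequence level. The adjusted p of 0.048 lies just inside the threshold and was lost under several alternatives, among them normexp, where the differences were larger, at 4.31, 4.43 and 4.71. The test borrows its spread from lines less noisy than MMS1. In the simulation with the measured SDs its region form called 414 unaltered regions higher and 450 lower, while 0 passed both tests. The simulated lines shared no probe effects and had a single SD per array, so neither the false calls nor that 0 settles the matter. A difference at these 3 is therefore not established.

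The 235 regions enriched in the positive lines were weighed first. A dye bias that follows intensity is argued against as the whole cause, since 81.7% of them were called again after loess, with the median moving from 1.6 (median SE 0.2) to 1.8 (0.18). In 200 regions picked from a pair of positive lines, the third positive line exceeded MMS1 by 1.67 (SD 0.43 over 3 choices). Probe effects common to any ChIP would not give this gap if the MMS1 ChIP had worked as well as the others. A single negative line cannot show that it did, so such effects are not excluded. Regions picked from MMS1 and a positive line were lower in the remaining lines by 1.23 than regions picked from positive pairs, which decides nothing, since MMS1 is the noisiest line and picking on its noise lowers the held-out values by itself. With each line in turn as the single line the real choice gave 235 and the highest of the others 0 (1 of 4 choices as large); 4 choices cannot give a share under 0.05, and the other choices place the noisiest line among the 3, raising their median SD from 0.26 to at least 0.31. With 1 negative line, a weaker immunoprecipitation or hybridisation in MMS1 cannot be told apart from the absence of IRF8. The same holds for any other difference between MMS1 and the positive lines. Binding of IRF8 therefore remains an open explanation.

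The 165 regions below input were weighed second. Whether a loess trend of ratio on intensity was the whole cause is not settled. Their median was -0.92 after loess (median SE 0.2), from -1.14 (0.17) before, and all 165 stayed below 0. That lay past the bound, but the bound was set after the values were seen and the regions were picked as low in the same data. By the share called again, 0 of the 165 were kept, against 81.7% of the enriched regions. The median size, its error and the prior degrees of freedom (8.02 before, 5.93 after) all moved against the calls. Their shares in ending the calls were not separated. The 165 regions were bright in input, with a median percentile of 99.3. The enriched regions were also bright, though less so, with a median percentile of 88.6. All 4876 windows at or above percentile 98 had a median of -0.72. That cut was the lower quartile of the 165 regions, so the 4876 include most of the windows they were compared with. Bright input signal is thus a candidate explanation for a large part of the pattern. Input is also the denominator of the ratio, which favours this outcome, and no biological explanation was tested.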

How the results depend on the processing

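The held-out comparison was added after seeing the data; the other alternatives were fixed before. Enriched regions stayed within 1.5 times of 235 under loess, normexp, Tukey centring, the authors' table, the median of probes, removal of dim probes, arrays fitted apart and a log2 minimum of 0.5; where a count moved, the cause was not tested. With arrays scaled to 1 MAD there were 854 enriched and 2266 below-input regions, 0 past both tests and 104 LY1 peak regions. In 300 bp windows these were 125 enriched, 13 below and 0 past both. In 1000 bp windows they were 494 enriched, 1056 below, 3 higher than MMS1 and 4 VAL peak regions. Normexp gave 8 below input, 0 past both and 1 MMS1 peak region; loess gave 0, 0, 1860 LY1 and 2 VAL peak regions. The median of probes gave 502 higher than MMS1, 889 lower and 94 past both. The trend and robust model gave 0 enriched, 0 below, 1241 higher, 3061 lower and 0 past both. Arrays fitted apart gave 258 below and 0 past both. Without dim probes LY1 had 89 peak regions and at a 1% rate 154. A fixed threshold of log2 1 gave 799 in LY1, 1671 in ODH1, 1591 in VAL, 5818 in MMS1 and 153 shared by the positive lines, 50 of them with MMS1 and 103 without. Leaving out each positive line in turn gave 102 to 1031 enriched, 4 to 1746 below, 0 to 3185 higher and 0 to 3420 lower than MMS1, and 0 to 495 past both; 2 lines leave 1 residual degree of freedom. The held-out difference of 1.67 became 2.26 with normexp and 1.02 in 1000 bp windows.

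At the named windows, 3 values changed sign, none past its test before or after. Enrichment on chromosome 1 (region from 52868103) moved from -0.13 to 0.29 with normexp and 0.29 with loess, and the difference on chromosome 7 (region from 20222788) from 2.76 to -1.35 in 300 bp windows. Of 476 enrichment values 419 kept direction and side of the threshold, 54 lost the call and 1 gained it; of 476 differences 348 kept both, 19 lost and 108 gained it. The list tests and their alternatives were not run, for lack of gene names. No paired analysis was possible because MMS1 is a single line. ChIP signal limits depth, and not only in MMS1. On the first and second designs, 42.8% and 51.8% of MMS1 ChIP probes were above the random-sequence level. For ODH1 the shares were 52.9% and 48%, and on the LY1 and VAL arrays they were 62% to 74.7%.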

Other observations

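The predictions of the tests of enriched regions reported here were written before their results were seen; the count for regions below input was added after. Enriched regions lay near one another more often than tested regions drawn at random: of 227 on autosomes, 24 (10.6%) had another within 100 kb, against a median of 8 in 10000 draws matched by array design (central 95% from 2 to 16; one-sided permutation p = 0.0012). Groups of 3 regions were found on chromosome 5 between 96164654 and 96297894, chromosome 6 between 32913244 and 32933226, chromosome 10 between 91048282 and 91167862, and chromosome 22 between 34885978 and 34979821. The regions below input did so too, with 49 of 165 (29.7%) against a median of 6 in the draws (central 95% from 0 to 12; p = 1e-04, the smallest the permutations can give), among them 9 on chromosome 4 between 8932487 and 8974702. By this count lying near one another was not particular to the enriched regions, provided that the regions below input are independent neighbours. The comparison does not settle whether both kinds cluster for the same reason. All 9 regions on chromosome 4 start at near-even steps, from 8932487, 8937233, 8941980 and 8946725 on to 8970451. Whether they are copies of 1 sequence was not tested, so they may not be independent neighbours. The count of 49 and its permutation p may therefore be inflated, and they are a weak control for the enriched regions.

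The enriched regions were not concentrated on any autosome: 0 of them passed Fisher's exact test after adjustment, the smallest adjusted p being 0.55. The smallest unadjusted p-values were 0.051 for chromosome 6, with 19 enriched of 1167 tested regions, and 0.055 for chromosome 18, with 0 of 348.

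The windows of the enriched regions lay nearer to a region's end than random windows of the same regions, with a median place of 0.42 on a scale from 0 at an end to 1 at the middle, against 0.49 in the draws (central 95% from 0.46 to 0.56). The regions below input had the same median place, 0.42. No draws were made from their own windows, so whether this placement sets enrichment apart is not settled.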
